A study of Lodderomyces parapsilosis with 6 samples.

How the data were processed

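The 6 samples were cells of Candida parapsilosis CLIB 214, of which 3 were controls and 3 received 15 mM tyrosol for 2 h after 4 h at 37 °C, per the labels. Poly-A RNA was made into TruSeq libraries and sequenced on an Illumina NextSeq instrument as single reads, per the labels' protocols. The submitters' processing notes name FastQC, STAR and DESeq without versions. The counting tool, the genome build, the use of strand and the treatment of reads shared between near-identical genes are not given in the sources used here, so values of members of gene families and of overlapping genes carry that uncertainty.

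The authors deposited 1 table of 5837 genes with estimated counts per library, per the file headers the raw values. Of these values 99.2% were not exactly whole, with no tolerance allowed, and low values fell in fractions of a read, so they were rounded to whole numbers for the count models. The deposited normalized values are on a log2 scale. For each library they equal the log2 of the raw value over a median-of-ratios size factor, minus the median of the gene, as tested on the table. The deposited log2 fold change is the difference of the group means of these values, the deposited fold change is its linear form with a sign, and the deposited p-value comes from a test that the headers do not name, with its Benjamini-Hochberg adjusted value beside it. The normalized values were not used in any test here. In the authors' deposited table, 1461 genes had an adjusted p under 0.05, 737 of them higher in tyrosol and 724 lower, and 1416 of the 1461 also passed in the model used here, with 1416 of them in the same direction. The table names genes by systematic identifier. Symbols were taken from the RefSeq gene table of assembly ASM18276v2, where 5824 identifiers matched and 2441 had a symbol. No coordinates were used except to order genes along the contigs. Mitochondrial genes had 20 entries. The share of counts summed over these entries, some of which may overlap, was at most 0.0490% in any library.

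Genes were kept with edgeR's filterByExpr at a minimum count of 10, which left 5791 and removed 46. Libraries were scaled by TMM, with factors from 0.978 to 1.05, and the groups were compared with edgeR's quasi-likelihood F test with robust estimation and Benjamini-Hochberg adjustment at 0.05 (R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0). The common biological coefficient of variation was 9.86%. The SE of a log2 fold change is its size divided by the square root of F, an approximation. CPM values are TMM scaled. On counts simulated for the 5791 genes from the means, spread and library sizes of these samples, 87 of 100 genes changed 1.5-fold and 96 of 100 genes changed 2-fold were recovered, with 14 false calls, which was 7.11% of the calls. The simulated genes were drawn independently and only these genes were changed. In the data 1691 genes passed and genes moved together between replicates, with an estimated correlation of 0.79 among cytosolic ribosomal proteins. The simulated rates may therefore not carry over. Totals of 19851780 to 44108139 counts leave little counting error for most genes, and the spread between samples sets the precision. Within each group, pairs of libraries differed by more than sampling noise, with a chi-square per degree of freedom from 13.3 to 65.5, so none was taken as a repeat deposit of another. This does not show that they came from separate cultures.

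The text draws most of its genes from a rule set before the data were examined. SUL2, MET10, MET15, MET16, MEP1, LAG1, cox1 and 2 further mitochondrial entries were named outside the rule, after their values were seen. The rule takes the 10 largest rises and 10 largest falls among changed genes that have a symbol, a mean level at or above the 25th percentile of tested genes (38.8 CPM) and all 3 tyrosol libraries on one side of the 3 controls. It adds at most 2 rising and 2 falling genes without a symbol, up to 2 changed members in each direction per list, and MRR1, MDR1, CDR1, CDR1B, TAC1, CAT1, SOD1, SOD2, GRE2, ARO10, ARO80, ERG11, FKS1, EFG1, BCR1, GCN4 and CAP1, of which 10 were found by symbol and the others are not analysed here under these names. The 28 gene lists were also set before the data were examined and filled by symbol only. Of the 1691 changed genes, 893 had no symbol and could enter no list. A list with at least 3 tested members was tested with limma's camera on log2 CPM with a preset correlation of 0.01, adjusted over 27 lists. The list of mitochondrially encoded and rRNA genes had 1 tested member and was not tested. Alternatives were an estimated correlation and limma's fry, which asks whether the genes of a list move one way and does not compare them with other genes.

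The gene counts, lists and named genes were recomputed with DESeq2's Wald test, with median-of-ratios factors, with scaling by library totals, without the filter, with a mean of at least 50 counts, with the replicate number as a block, and without each library in turn. The gene counts alone were also taken with a 1.5-fold or an adjusted p of 0.01 threshold and from the authors' deposited comparison. Lists under DESeq2 were tested with limma's cameraPR on the Wald statistics, at the same preset correlation. A change of pseudocount applies only to normalized values and was not run. Added after the data were seen were a fit with tyrosol replicate 1 thinned to the mean total of the other libraries, a fit with a trend in coding length removed, and the respiratory list without cox1. Of the lengths in the gene table, 95.9% were multiples of 3, so they are called coding lengths. The others do not make up whole codons, so for those genes the name is only approximate.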

Results

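The study measured the transcriptome of Candida parapsilosis, an opportunistic yeast pathogen, after exposure to tyrosol, an aromatic alcohol derived from tyrosine that Candida species release as a quorum-sensing molecule. Wild-type cells of strain CLIB 214 were grown in rich medium at 37 °C for 4 h, and 3 samples then received 15 mM tyrosol for 2 h while 3 control samples did not. Poly-A RNA of the 6 samples was sequenced, and the estimated read counts of 5837 genes were compared between the groups. The totals were 20215737, 21420996 and 24099776 counts in control replicates 1 to 3 and 44108139, 23432328 and 19851780 counts in tyrosol replicates 1 to 3, so that tyrosol replicate 1 was the deepest library. The comparison asked which genes changed their mRNA level with tyrosol. Values below are CPM (the standard scaling of counts to library size, here with TMM factors) given as mean ± SD with n = 3 libraries per group, and log2 fold changes of tyrosol over control with their SE. The edgeR p-values measure the spread between these 6 samples, and nothing in the labels says from how many separate experiments they came. The camera p-values with a preset correlation compare list members with the other genes and do not measure that spread.

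With tyrosol, the glycolysis and oxidative stress defence lists were higher, and the lists of cytosolic ribosomal proteins and ribosome biogenesis were lower, by camera with a preset correlation. With an estimated correlation none of the 4 passed (adjusted p = 0.408 for oxidative stress defence and adjusted p = 0.520 for each of the other 3). A two-sided exact permutation of the list means over the 6 libraries gave p = 0.1 for each of the 4, the smallest possible. Reads of the 74 cytosolic ribosomal protein genes made up 11.6% to 11.7% of all counts in the control libraries and 7.47% to 8.71% in the tyrosol libraries. Reads of the 14 glycolysis genes made up at most 1.66% in the control libraries and 2.43% to 2.82% in the tyrosol libraries. Among 5791 genes tested with edgeR's quasi-likelihood test, 1691 passed a Benjamini-Hochberg adjusted p of 0.05, with 850 higher and 841 lower in tyrosol. Of these, 274 were at least 1.5-fold higher and 171 at least 1.5-fold lower, and 114 and 56 reached a change of at least 2-fold. The first principal component of the log2 CPM values held 66.6% of the variance and separated the groups. The second held 15.1% and ran between tyrosol replicate 1 and tyrosol replicate 3. The number of changed genes fell to 1123 without control replicate 1 and to 1020 without control replicate 2, and was 847 at an adjusted p of 0.01. The genes higher in tyrosol numbered 527 without control replicate 2, and the genes lower in tyrosol 535 without control replicate 1, 493 without control replicate 2 and 555 without tyrosol replicate 2.

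**Figure D1:**
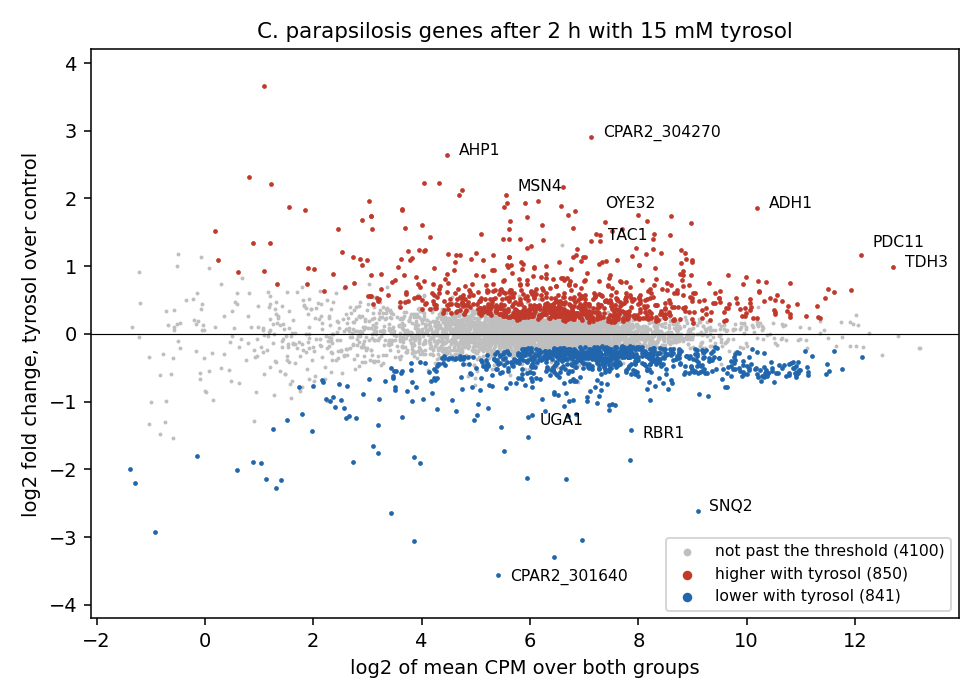
Each point is a gene, with the log2 of its mean CPM over both groups on the horizontal axis and its log2 fold change of tyrosol over control on the vertical axis. Red and blue points are the 850 genes higher and 841 genes lower in tyrosol (edgeR, adjusted p under 0.05), grey points did not pass, and 1 grey gene lies outside the vertical axis.

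The 10 largest rises with tyrosol among genes with a symbol and a mean level at or above the 25th percentile were those of MSN4, TRY6, ADH1, OYE32, KNS1, ADH5, TEC1, HSP30, SAP10 and LEU42. MSN4, a zinc finger factor related to yeast stress regulators, rose from 18.2 ± 2.29 to 76.2 ± 16.3 CPM (log2 fold change 2.06 ± 0.17, edgeR adjusted p = 8.13e-05). OYE32, an NADPH oxidoreductase of the old yellow enzyme family, rose from 178 ± 20.9 to 599 ± 66.1 CPM (log2 fold change 1.75 ± 0.11, edgeR adjusted p = 2.08e-05). The alcohol dehydrogenase gene ADH1 rose 3.62-fold, from 507 ± 163 to 1838 ± 711 CPM, and ADH5 rose 3.16-fold, from 138 ± 10.6 to 436 ± 79.9 CPM. TEC1, a transcription factor of filamentation and biofilm growth in Candida albicans, rose 2.96-fold to 165 ± 26.2 CPM. SAP10, a gene of the secreted aspartyl protease family, rose 2.92-fold, LEU42, of leucine synthesis, 2.79-fold, the kinase gene KNS1 3.17-fold, TRY6 3.67-fold and HSP30 2.93-fold. Of the genes without a symbol that met the same conditions, CPAR2_304270 and CPAR2_503940 rose the most, by 7.54-fold and 4.52-fold.

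Among changed genes with a symbol and a mean level at or above the 25th percentile, SNQ2 fell the most. SNQ2 is an ABC transporter gene of the drug efflux family. It fell from 941 ± 16.7 to 154 ± 7.03 CPM (log2 fold change -2.61 ± 0.06, edgeR adjusted p = 2.03e-07). RBR1, a cell wall protein gene, fell from 338 ± 10.2 to 126 ± 34.8 CPM (log2 fold change -1.42 ± 0.16), and UGA1, a GABA transaminase gene, from 242 ± 4.10 to 112 ± 7.28 CPM (log2 fold change -1.12 ± 0.07). The fatty acid desaturase gene FAD3 fell from 255 ± 25.4 to 123 ± 21.0 CPM. IDP2, an isocitrate dehydrogenase gene, and PDE2, a cAMP phosphodiesterase gene, fell with log2 fold changes of -0.97 ± 0.07 and -0.88 ± 0.13. The sulfur assimilation genes ECM17 and MET3 fell with log2 fold changes of -0.93 ± 0.07 and -0.92 ± 0.17, and the methionine permease gene MUP1 with -0.87 ± 0.10. The ribosomal protein gene RPL38 completed these 10 falls, from 821 ± 57.1 to 435 ± 133 CPM. Of the genes without a symbol that met the same conditions, CPAR2_301640 and CPAR2_108370 fell the most, with log2 fold changes of -3.55 ± 0.12 and -3.30 ± 0.19. The edgeR adjusted p of each of the falls in this paragraph was 0.00988 or smaller.

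**Figure D2:**
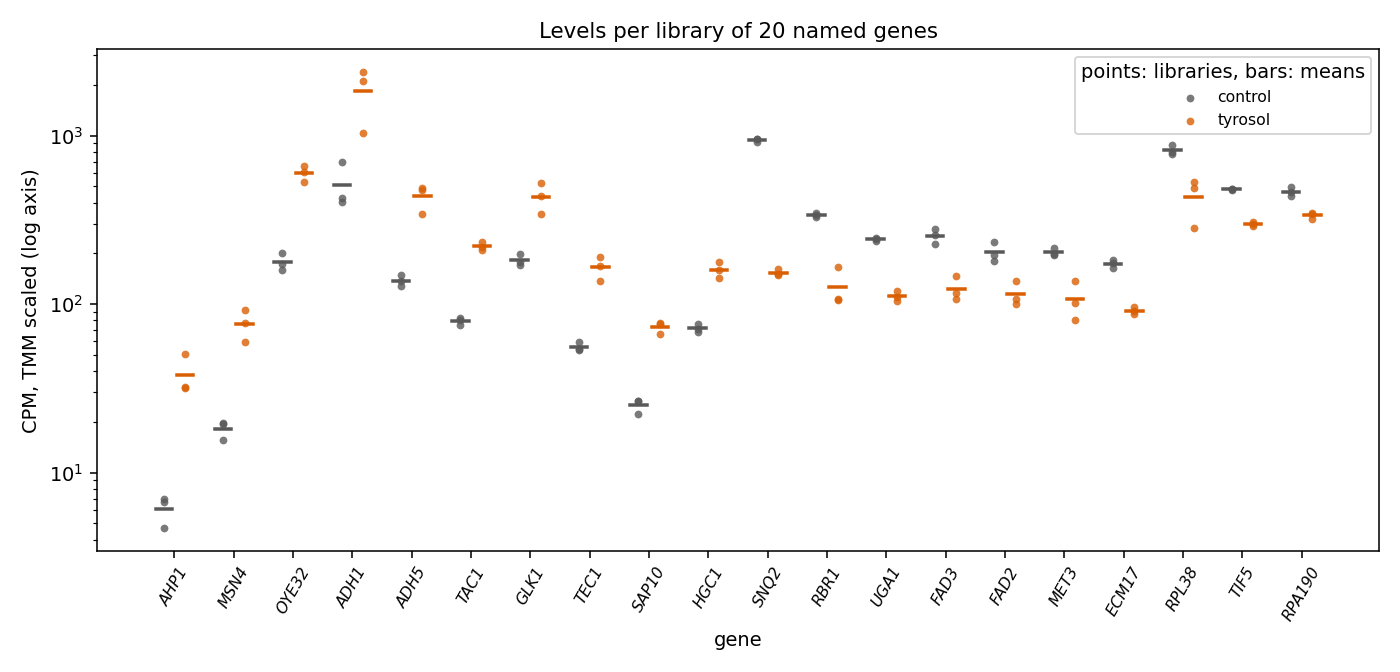
TMM-scaled CPM on a log axis of 20 named genes, where each point is a library, grey for control and orange for tyrosol, and bars are the means of 3 libraries. In each of these genes the 3 tyrosol libraries lie on one side of the 3 controls, such as SNQ2 with means of 941 and 154 CPM. For those among the 10 largest rises and 10 largest falls, SNQ2 included, this separation was a condition of their selection.

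The genes of the cytosolic ribosome fell together. All 74 tested ribosomal protein genes were lower in tyrosol past the threshold, both over all genes and adjusted over the list alone, with a median log2 fold change of -0.55 (camera adjusted p = 1.29e-26, and adjusted p = 0.520 with an estimated correlation). RPP2A, of the ribosomal stalk, fell from 477 ± 31.8 to 271 ± 41.7 CPM. The mean of the list, relative to the control mean, lay between -0.73 and -0.42 in the tyrosol libraries and between -0.02 and 0.02 in the control libraries on the log2 scale. Of 68 ribosome biogenesis genes, 45 fell, 0 rose and 23 did not pass, and 59 fell when adjusted over the list alone (median -0.34, camera adjusted p = 5.33e-14, and adjusted p = 0.520 with an estimated correlation). Among them the RNA helicase gene DBP2 fell from 438 ± 54.9 to 264 ± 48.4 CPM. The 45 became 26 without control replicate 1, 28 without control replicate 2 and 23 without tyrosol replicate 2.

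Other parts of protein synthesis were lower as well. Of 37 genes of translation factors and tRNA synthetases, 25 fell, 0 rose and 12 did not pass, with 30 falling when adjusted over the list alone (median -0.27, camera adjusted p = 1.47e-10, and adjusted p = 0.520 with an estimated correlation). TIF5, a translation initiation factor gene, fell from 480 ± 4.31 to 300 ± 8.94 CPM, and the lysyl-tRNA synthetase gene KRS1 from 699 ± 18.0 to 490 ± 30.6 CPM. Of 13 genes of RNA polymerases I and III, 7 fell, 0 rose and 6 did not pass, with 11 falling when adjusted over the list alone (median -0.29, camera adjusted p = 0.000729, and adjusted p = 0.520 with an estimated correlation). RPA190, the largest subunit of RNA polymerase I, fell from 466 ± 28.4 to 336 ± 15.5 CPM. Of 18 mitochondrial ribosomal protein genes, 12 fell, 0 rose and 6 did not pass, with 13 falling when adjusted over the list alone (median -0.26, camera adjusted p = 0.000255, and adjusted p = 0.353 with an estimated correlation). These counts rested on single libraries in part: without control replicate 2 they were 15, 4 and 6, without control replicate 1 the RNA polymerase and mitochondrial counts were 4 and 6, and without tyrosol replicate 2 they were 4 and 7. The RNA polymerase count was also 4 when libraries were scaled by their totals only.

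Glycolysis genes rose together. All 14 tested genes were higher in tyrosol past the threshold, both over all genes and adjusted over the list alone, with a median log2 fold change of 0.76 (camera adjusted p = 3.52e-09, and adjusted p = 0.520 with an estimated correlation). GLK1, a glucokinase gene, rose from 183 ± 14.8 to 435 ± 89.2 CPM, and PFK1, of phosphofructokinase, from 287 ± 32.1 to 595 ± 132 CPM. The mean of the list lay between 0.54 and 0.86 in the tyrosol libraries and between -0.06 and 0.09 in the control libraries on the log2 scale. Of 9 fermentation and acetate genes, 4 rose, among them ADH1 and ADH5, 0 fell and 5 did not pass, with 4 rising and 2 falling when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.244).

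Of 25 oxidative stress defence genes, 12 rose, 2 fell and 11 did not pass, with 13 rising and 3 falling when adjusted over the list alone. The list passed as higher (median 0.26, camera adjusted p = 0.00133, and adjusted p = 0.408 with an estimated correlation). AHP1, a peroxiredoxin gene, rose 6.27-fold, from 6.09 ± 1.23 to 38.2 ± 10.8 CPM, and CAP1, an AP-1 type transcription factor of the oxidative stress response, rose 1.62-fold, from 133 ± 9.68 to 216 ± 13.9 CPM. TRX2, a thioredoxin gene, and GTT13, of a glutathione transferase family, were the 2 that fell, with log2 fold changes of -1.22 ± 0.22 and -0.78 ± 0.19, and without control replicate 2 the fall of GTT13 did not pass, which left 1. SOD2, of superoxide dismutase, stood at 415 ± 12.3 CPM in control and 448 ± 33.0 CPM in tyrosol (edgeR adjusted p = 0.259).

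Of 37 respiratory chain and ATP synthase genes, 11 rose, 0 fell and 26 did not pass, also when adjusted over the list alone. The list passed as higher (median 0.15, camera adjusted p = 0.000130, and adjusted p = 0.520 with an estimated correlation). NDE1, an NADH dehydrogenase gene, rose from 944 ± 96.1 to 1458 ± 177 CPM, and COX13, of cytochrome c oxidase, from 579 ± 18.7 to 793 ± 14.9 CPM. The mean log2 fold change of the list was -0.04, against the sign of its median, because it holds the mitochondrially encoded gene cox1 at -7.81, which did not pass (edgeR adjusted p = 0.164) and whose counts came almost wholly from control replicate 2. The mean of the list lay between 0.03 and 0.10 in the tyrosol libraries and between -0.07 and 0.13 in the control libraries on the log2 scale, with control replicate 2 above every tyrosol library, so the groups overlapped (two-sided exact permutation p = 0.4, where the design allows no p under 0.1). Without cox1, a setting chosen after the data were seen, the mean lay between 0.11 and 0.21 in the tyrosol libraries and between -0.02 and 0.03 in the control libraries. The 11 became 6 without control replicate 1, 4 without control replicate 2, 5 without tyrosol replicate 2, 18 with scaling by library totals and 6 with a coding length trend removed.

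Of 38 genes of DNA replication and the cell cycle, 8 fell, 3 rose and 27 did not pass, also when adjusted over the list alone. The list passed as lower (median -0.15, camera adjusted p = 0.0176, and adjusted p = 0.408 with an estimated correlation). It did not pass when tested on DESeq2's Wald statistics (cameraPR adjusted p = 0.158). CDC5, a polo-like kinase gene, fell from 234 ± 21.8 to 172 ± 6.17 CPM, while HGC1, a G1 cyclin-related gene of hyphal growth in Candida albicans, rose from 71.8 ± 3.91 to 160 ± 17.4 CPM and the G1 cyclin gene CCN1 from 141 ± 8.70 to 199 ± 2.78 CPM. The 8 falls became 3 without control replicate 2 and 5 without control replicate 3.

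**Figure D3:**
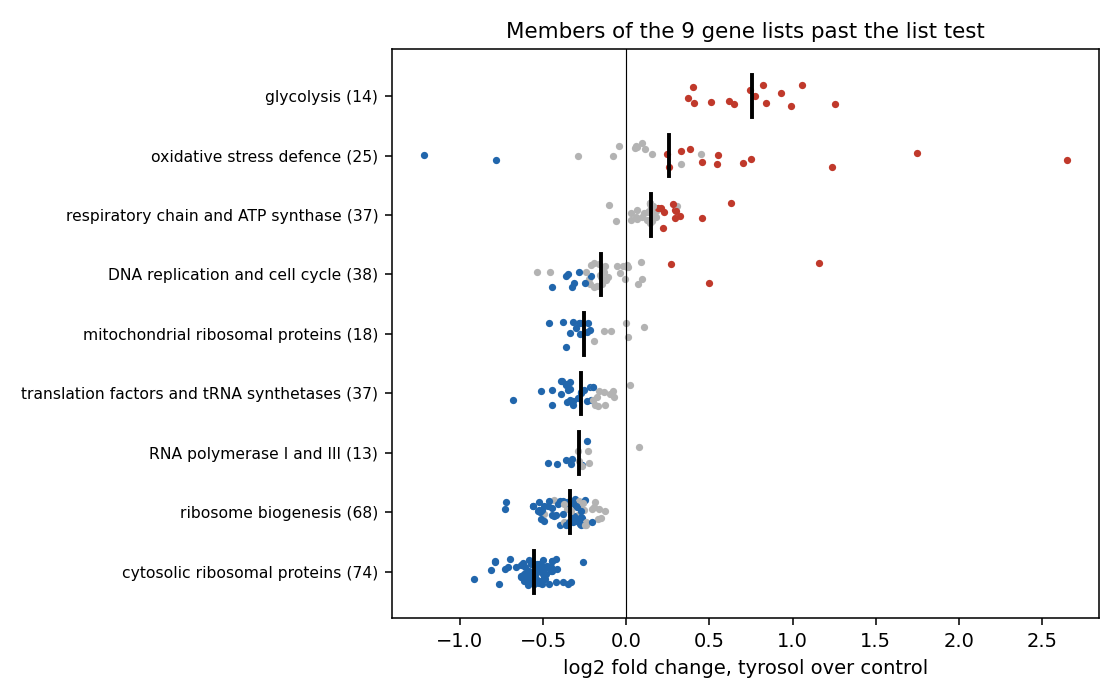
Log2 fold change of tyrosol over control of each tested member of the 9 lists past the list test, 1 point per gene, with red for higher, blue for lower and grey for not past the threshold, and black bars at the list medians. The 74 ribosomal protein genes all lie below 0 and the 14 glycolysis genes all above 0; cox1, at -7.81 in the respiratory list, lies outside the axis.

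Drug efflux genes and their regulators moved in both directions. Of 15 genes, 4 rose, 4 fell and 7 did not pass, with 4 rising and 5 falling when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.484). CDR1, CDR1B and MDR1 were not found under these symbols, so the list does not cover them. TAC1, whose Candida albicans relative activates ABC transporter genes, rose from 79.2 ± 3.81 to 220 ± 12.5 CPM (log2 fold change 1.48 ± 0.07, edgeR adjusted p = 4.88e-06), in the libraries where SNQ2 was lower. The ABC transporter gene ABC1 rose from 335 ± 29.7 to 509 ± 56.9 CPM, and CDR3 fell by 0.43 on the log2 scale. MRR1, of a regulator of multidrug transporters, was at 72.8 ± 2.39 CPM in control and 68.4 ± 7.37 CPM in tyrosol (edgeR adjusted p = 0.486). ERG11, the azole target, was at 205 ± 10.6 and 205 ± 26.2 CPM (edgeR adjusted p = 0.989). Of the 25 ergosterol genes, 4 rose and 2 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.484), with ERG251 at 73.3 ± 17.5 CPM in control and 143 ± 32.4 CPM in tyrosol (edgeR adjusted p = 0.00771).

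Tyrosol is a product of the Ehrlich pathway, which turns aromatic amino acids into alcohols. Of 20 genes in the list for this pathway and aromatic amino acid synthesis, 5 rose, 6 fell and 9 did not pass. Adjusted over the list alone, 5 rose and 7 fell, and the list did not pass (camera adjusted p = 0.484). Its largest rise was that of GAP2, from 1.28 ± 0.133 to 3.33 ± 0.922 CPM, which is also in the permease list. The alcohol dehydrogenase genes ADH1 and ADH5 are counted in the fermentation list. The counts are thus those of the list and not of the pathway alone. ARO10, of a phenylpyruvate decarboxylase, rose from 44.2 ± 1.51 to 61.1 ± 3.63 CPM, and ARO4, of the entry step of aromatic amino acid synthesis, fell from 383 ± 8.25 to 287 ± 13.7 CPM. ARO80, of a regulator of aromatic amino acid use, was at 41.1 ± 2.65 and 44.5 ± 10.8 CPM (edgeR adjusted p = 0.624). Of 55 amino acid synthesis genes, 6 rose and 11 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0624). LEU42 and GDH3, the latter at 170 ± 64.2 CPM in control and 451 ± 111 CPM in tyrosol, were among the rises, and MET3 and MET14 among the falls. GCN4, a regulator of amino acid synthesis, was at 817 ± 27.4 and 750.3 ± 81.2 CPM (edgeR adjusted p = 0.310). Of 19 amino acid permease and oligopeptide transporter genes, 4 rose and 4 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.706), with AGP3 falling by 1.14 on the log2 scale.

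The remaining lists did not pass the list test, though single members changed. Of 26 biofilm and morphology regulators, 4 rose, TEC1 among them, and 1 fell, with 3 and 1 when adjusted over the list alone (camera adjusted p = 0.531), while EFG1 stood at 195 ± 38.4 and 172 ± 29.2 CPM (edgeR adjusted p = 0.442) and BCR1 at 100.1 ± 5.75 and 89.0 ± 15.0 CPM (edgeR adjusted p = 0.291). Of 77 cell wall and adhesion genes, 15 rose and 10 fell, with 15 and 13 when adjusted over the list alone (camera adjusted p = 0.706), and MKC1, a MAP kinase gene of cell wall integrity, fell from 137 ± 9.88 to 86.4 ± 7.51 CPM. Of 17 trehalose, glycerol and osmotic stress genes, 6 rose and 1 fell, with 7 and 2 when adjusted over the list alone (camera adjusted p = 0.0812), and RHR2, of glycerol phosphatase, rose from 345 ± 20.9 to 565 ± 77.0 CPM. Of 8 hexose transporter and sensor genes, 2 rose and 4 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.244), with HGT17 falling by 1.34 on the log2 scale. Of 10 fatty acid synthesis and desaturation genes, 2 rose and 5 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.308), and FAD2 fell from 203 ± 26.8 to 115 ± 19.4 CPM. Of 8 secreted hydrolase genes, 3 rose and 3 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.939), with PLC2 falling by 0.81 on the log2 scale.

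In carbon use, 4 of 20 tricarboxylic acid cycle genes rose and 3 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.706), with IDP1 rising 1.76-fold beside the fall of IDP2. Of 8 genes of gluconeogenesis and the glyoxylate cycle, 2 rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.484), namely MDH1-3 and MLS1 upward and the isocitrate lyase gene ICL1 downward. Of 30 beta-oxidation and peroxisome genes, 1 rose and 2 fell, with 1 and 1 when adjusted over the list alone (camera adjusted p = 0.706). Of 26 chaperone and heat shock genes, 3 rose, HSP30 among them, and SSB1 was the 1 that fell, with 1 and 1 when adjusted over the list alone (camera adjusted p = 0.484). Of 16 iron genes, 1 rose and 2 fell, with 1 and 1 when adjusted over the list alone (camera adjusted p = 0.905), and the riser was the ferric reductase family gene FRE9. Of 59 proteasome and autophagy genes, 8 rose and 0 fell, with 4 and 0 when adjusted over the list alone (camera adjusted p = 0.615), and the vacuolar protease gene PRB1 rose 1.40-fold. The median and the mean log2 fold change differed in sign in 4 of these lists: Ehrlich and aromatic amino acid genes (-0.10 and 0.004), permeases (0.01 and -0.05), chaperones (-0.04 and 0.01) and secreted hydrolases (-0.08 and 0.09).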

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

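The thinning of tyrosol replicate 1, the removal of a coding length trend and the respiratory list without cox1 were chosen after the data were seen. Across the settings run, no called list and no named gene past the threshold reversed direction. The counts of changed, higher and lower genes moved by over 1.5 times with stricter thresholds, by construction: at least 1.5-fold gave 445, 274 and 171, and an adjusted p of 0.01 gave 847, 448 and 399. Leaving out 1 library gave 1020 to 1751 changed, 527 to 856 higher and 493 to 895 lower genes, some of them moves of over 1.5 times. The size of the move depended on the library: 1020 genes changed without control replicate 2, 1658 without tyrosol replicate 1 and 1751 without tyrosol replicate 3. With the replicate number as a block, 1070 genes changed, 539 higher and 531 lower. Controls and tyrosol samples of the same number deviated in opposite ways across genes (correlations of -0.20, -0.24 and -0.37), and no sample correlated best with its own number, so the numbers are not taken as pairs; under the block 9 lists passed as in the fit without it. Among these 9, counts of changed members that moved by over 1.5 times under the block were 45 to 26 falls in ribosome biogenesis, 7 to 4 falls in RNA polymerase I and III, 11 to 5 rises in the respiratory chain and 8 to 4 falls in DNA replication and cell cycle. DESeq2 gave 1924 changed genes, scaling by library totals 1587, the thinned library 1683 and the coding length correction 1726, while the authors' deposited comparison held 1461. Over scalings the median log2 fold change of all genes stayed between -0.02 and 0.02.

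The 9 lists became 0 with an estimated correlation and 15 with fry, which asks another question. With an estimated correlation the adjusted p was 0.520 for cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerase I and III, translation factors, glycolysis and the respiratory chain, 0.353 for mitochondrial ribosomal proteins, and 0.408 for oxidative stress defence and for DNA replication and cell cycle. The estimated correlations ranged widely over these 9 lists, from 0.79 for cytosolic ribosomal proteins and 0.78 for glycolysis to 0.0028 for mitochondrial ribosomal proteins and -0.01 for DNA replication and cell cycle. The last 2 lie under the preset 0.01, so shared movement between replicates does not account for those losses. With an estimated correlation, camera uses the few residual degrees of freedom of the 6 libraries. With a preset one it uses degrees of freedom set by the number of genes. For these 2 lists the unadjusted camera p went from 5.67e-05 to 0.0131 and from 0.00587 to 0.0322. The losses with an estimated correlation are thus not an effect of correlation alone. DNA replication and cell cycle was also lost with DESeq2 (adjusted p = 0.158), and the cause was not tested. Leaving out 1 library ended no list call, and 3 calls of further lists were gained in such fits, 1 with DESeq2, 1 with scaling by library totals and 6 with fry. Among named genes, leaving out 1 library ended 63 calls in 606 comparisons. The block ended 13 calls in 101 comparisons, scaling by library totals 4, median-of-ratios factors 1 and the coding length correction 1. These comparisons include ARO80, SOD2, ERG11, GCN4, MRR1, BCR1 and EFG1, which had not passed and so had no call to lose. With tyrosol replicate 1 thinned, no call among the 101 named genes changed, and the effect of depth was not tested otherwise.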

Other observations

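The tests of gene groups other than the fixed lists, with which they share some members, and the test of random gene orders were chosen after the results were seen. Of 7 such groups, that of sulfate assimilation and methionine uptake held 9 falls and 0 rises among 12 genes, with a median log2 fold change of -0.50 (camera adjusted p = 7.93e-06 over the 7 groups, and adjusted p = 0.0803 with an estimated correlation). It was drawn up because some of these genes had been seen to fall, so these values partly restate that. Without MET3, MET14, ECM17, SUL2 and MUP1, the 5 noticed first, 4 of the other 7 genes fell, 0 rose and 3 did not pass, with a median of -0.28 (camera unadjusted p = 0.00244, and unadjusted p = 0.0355 with an estimated correlation), in the same libraries. Of those 7, MET10, MET15 and MET16 are also in the fixed list of amino acid synthesis, whose values were already part of the results. MET10 and MET15 are among the 4 falls, so these p-values are not independent support. Besides MET3, ECM17, MET14 and MUP1, the sulfate permease gene SUL2 fell from 12.2 ± 1.04 to 6.29 ± 0.826 CPM and the sulfite reductase gene MET10 from 131 ± 7.48 to 81.2 ± 12.9 CPM (mean ± SD, n = 3). The other 6 groups did not pass. Purine synthesis had 0 rises and 2 falls among 11 genes (camera adjusted p = 0.396), and nitrogen and GABA use 4 and 2 among 21 (0.956), with the ammonium permease gene MEP1 at 32.1 ± 9.01 CPM in control and 64.1 ± 12.2 CPM in tyrosol. The sphingolipid group had 4 rises and 3 falls among 14 genes (0.956). Its falls were the ceramide synthase gene LAG1, from 113 ± 17.0 to 62.2 ± 12.0 CPM, and the fatty acid desaturase genes FAD2 and FAD3, which are also in the fixed list of fatty acid synthesis and desaturation. DNA repair had 3 and 1 among 31 genes (0.956), cAMP and glucose signalling 1 and 5 among 17 (0.956), and zinc cluster factors 0 and 0 among 19 (0.894).

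The fall of cytosolic ribosomal protein genes was set against technical explanations. Their genes are short (median length 672.5, against 1287 over all genes) and abundant. That median cannot arise if all their lengths are multiples of 3, so a match on coding length is only approximate for them. They were set against 20 genes each of like length and level outside the ribosome and translation lists. Their median log2 fold change was lower by -0.65 (95% bootstrap interval -0.67 to -0.61). This argues against a bias of level, or of length as the gene table gives it, as the whole cause. That interval is narrower than the range of the list means of the tyrosol libraries, -0.73 to -0.42, so it does not measure the spread between samples. No single library carried the fall, since the highest list median over the 6 fits without 1 library was -0.46. Scaling by library totals left the median at -0.53. GC content was not analysed here, and growth state at harvest was not measured, so slower growth with tyrosol remains an untested hypothesis.

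The rise of glycolysis genes was tested in the same way. Against 20 genes each of like coding length and level, their median log2 fold change was higher by 0.75 (95% bootstrap interval 0.67 to 0.86), and the lowest list median over the 6 fits without 1 library was 0.66. Both argue against a length or level bias, or a single library, as the cause. The bootstrap interval is narrower than the range of the list means of the tyrosol libraries, 0.54 to 0.86, so it does not measure the spread between samples. Exposure to tyrosol is the difference the design names, and a shift in carbon use may go with it, but GC content was not analysed here and no metabolite was measured.

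Strongly changed genes often lay next to each other. Of 169 changed genes with a change of at least 2-fold that could be placed along the contigs, 41 formed 22 neighbouring pairs with the same direction, 14 higher and 8 lower. Random orders of the genes gave 0 to 6 pairs in their central 95%, and 0 of 10000 gave as many (permutation p = 0.0001, the smallest they can give), which argues against a chance order. Reads spilling from one gene onto the next may account for part of it. In the median pair the less abundant gene had 11.1% of the change in CPM of the other (95% bootstrap interval 5.26% to 61.5%), and the share was above 20% in 8 pairs. That interval lies above the 5% set beforehand as the mark of spill alone, but the median lies under the 20% set for excluding it. Spill and shared regulation therefore cannot be told apart over these pairs.

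The real grouping gave 1691 changed genes and the highest of the other splits gave 0. It was the 1 of 10 splits of the 6 libraries with as many, and with 10 splits the share cannot fall below 0.1. Every other split puts libraries of both conditions in each group, so the difference between conditions adds to the spread within groups. The 0 therefore does not show how many calls would arise without an effect.

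The mitochondrially encoded gene cox1 had 4380 estimated counts in control replicate 2 and 6.17 to 21.2 in the other 5 libraries, and 2 further mitochondrial entries, CapafMp06.1 and CapafMp06.2, had 3862 and 2253 counts in that library and at most 9.67 in the others.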
